A study of Bos grunniens with 18 samples.

How the data were processed

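The study profiled N6-methyladenosine by antibody enrichment and sequencing (MeRIP-seq) in the caput, corpus and cauda of the epididymis, with 3 RIP and 3 input libraries per region. Per the labels' protocols, 6 adult yaks were used, mRNA was captured with oligo-dT beads and fragmented, second strands were made with dUTP, and libraries were read as pairs on an Illumina NovaSeq instrument. The labels do not say which animal gave which library, so the spread within a region could be technical. Trimmomatic, HISAT2 and deepTools are named in the submitters' processing notes, without versions. The peak caller, the differential test, the site predictor and the genome build are not given in the sources used here.

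Each region has 1 list of candidate adenosines with the authors' prediction score and class, per the file headers. The deposited combined score separates the classes at 0.557 (low), 0.584 (moderate), 0.62 (high) and 0.676 (very high confidence), as found from the values. Many lines are repeated, so each position was counted once with its highest score. A position listed in more than 1 region had the same highest score in each (0 of 97619 differed), so the score says nothing of how strongly a region was methylated. For each pair of regions, a deposited table gives per site the authors' p-value and adjusted p-value. In these comparison tables a site is a whole peak, not a single adenosine. It also gives the authors' ratio (fold) between the regions and its log2 value, per the file headers. Whether these folds are relative to the input libraries is not given in the sources used here, so a difference in methylation is not separated from one in transcript abundance. Folds are first-named over second-named region: unspliced sites whose candidates are listed in the first region but not the second had positive median log2 folds (0.32, 0.39 and 0.40 for corpus over caput, cauda over caput and cauda over corpus), and the reverse sites negative ones. The p-values of 13 sites are listed as 0 and may be placeholders. The deposited table of expression values has 9 columns whose codes match no label. These 9 columns were not used in any step, so the planned expression tests, the comparison of m6A with expression and the expression filter on named genes were not run. From that table only the symbols, ontology terms and pathways were taken, and 9319 of the 9629 gene identifiers of the comparison tables had a symbol. Motif analysis was not run, since no genome was used here.

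Peaks of different regions were compared with bedtools 2.31.1 by an overlap of at least 1 base. The lists carry no strand, so the planned restriction to the same strand was not applied, and peaks run from first to last base, introns included. Coordinates are printed counting from 1. Shares have 95% Wilson intervals (statsmodels 0.14.6). Positions were assigned to genes through the site spans of the comparison tables (intervaltree 3.1.0).

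Differential sites were counted in the deposited tables at an unadjusted p under 0.05, as set before the data were examined, and at an adjusted p under 0.05. A site is called higher or lower only at the adjusted threshold. The rule for named sites, also set before, takes per comparison the 5 highest and 5 lowest log2 folds at an unadjusted p under 0.05 in genes with a symbol, and up to 6 sites in genes of the fixed lists by lowest p. The planned naming of sites by enrichment within a region was not applied, since the lists carry no such value. Other list sites, and the genes listed in a single region, were named after their values were seen.

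The 21 gene lists, with 513 entries, were fixed before the data were examined. They were meant for expression values. Their test on the sites of the comparison tables, and the use of the adjusted threshold for it, were chosen after the data were seen. It counts genes with a called site in 1 direction and takes the exact one-sided hypergeometric probability within strata of sites per gene (1 to 5 or more), convolved over strata. The background is every gene with a site in that comparison. Lists with at least 3 such genes were tested, at both thresholds, with Benjamini-Hochberg adjustment over the 112 tests of each. Ontology terms and pathways with 10 to 500 genes were tested in the same way at both thresholds, adjusted over 19924 tests. Genes listed in a single region were tested likewise, within strata of candidate positions per gene. "Adjusted over the list alone" applies Benjamini-Hochberg to the authors' p-values of the list's sites.

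The list test was tested on simulated data: with calls drawn in proportion to sites per gene, lists of 10 genes had p under 0.05 in 3.2% (corpus over caput, 7973 genes), 0.2% (cauda over caput, 8070 genes) and 0.4% (cauda over corpus, 7939 genes) of 500 simulations, and in 100% when 4 genes were planted. Planted genes were set as called, so the 100% follows from the design and is no measure of power. The simulation ignores overlapping sites and covers no choice of threshold made after the data were seen. Computation used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9, with random seed 1. Alternatives were a stricter confidence class (in place of a stricter enrichment, which the lists do not give), a reciprocal overlap, other thresholds on p and fold, and, added after the data were seen, repeated lines, positions in place of peaks, sites with folds near 1 left out, and the list test without strata, with each gene in the direction of its lowest-p site, with overlapping sites of 2 genes counted once and without sites with p listed as 0.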

Results

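N6-methyladenosine (m6A), a methyl mark on adenosines of messenger RNA, was mapped along the epididymis of healthy adult male yaks (Bos grunniens). The epididymis is the duct in which sperm mature after leaving the testis, and it was divided into its head (caput), body (corpus) and tail (cauda). Fragmented poly(A) RNA was enriched with an antibody against m6A, and the enriched (RIP) and unenriched (input) RNA were sequenced. The 18 libraries comprised 3 RIP and 3 input libraries for each of the 3 regions. The results below rest on 1 list of candidate m6A sites per region and on 3 tables in which the authors compared the sites of a pair of regions. A site of those comparisons is a whole peak (median length 251 bases), not a single adenosine. These tables carry no values per library, so no replicate error can be given, and the sequencing depth behind each site is unknown. The genome build is not given in the sources used here, and exon or untranslated-region classes were not analysed here.

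The first question was how many m6A sites each region carried and how far the regions shared them. The candidate list of the caput held 103462 adenosine positions in 14542 peaks, that of the corpus 99547 positions in 13798 peaks and that of the cauda 103697 positions in 14182 peaks. Of these positions, 19758 in the caput (19.1%, 95% Wilson interval 18.9 to 19.3), 19197 in the corpus (19.3%, 19.0 to 19.5) and 19786 in the cauda (19.1%, 18.8 to 19.3) were classed by the authors as m6A sites of low to very high confidence. The intervals cover counting error only. The 3 shares differed by less than the width of these intervals. Similar shares are partly built in, since 97619 positions were in more than 1 list, each with the same score. They therefore do not compare methylation between regions.

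Most peaks were shared between regions. By at least 1 base, 79.1% of corpus peaks overlapped a caput peak, 77.6% of cauda peaks overlapped a caput peak and 76.0% of cauda peaks overlapped a corpus peak. When each peak had to cover at least 50% of the other, these shares were 58.5%, 57.2% and 55.9%. Across the regions 143390 positions were listed, of which 65697 (45.8%) were listed in all 3 regions and 45771 (31.9%) in a single region. Positions listed in all 3 regions were classed as m6A sites in 20.0% of cases (95% Wilson interval 19.7 to 20.3) and positions listed in a single region in 17.2% (16.8 to 17.5). The very high confidence class made up 2.43% of the positions of all 3 regions and 1.37% of those of a single region.

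**Figure D1:**
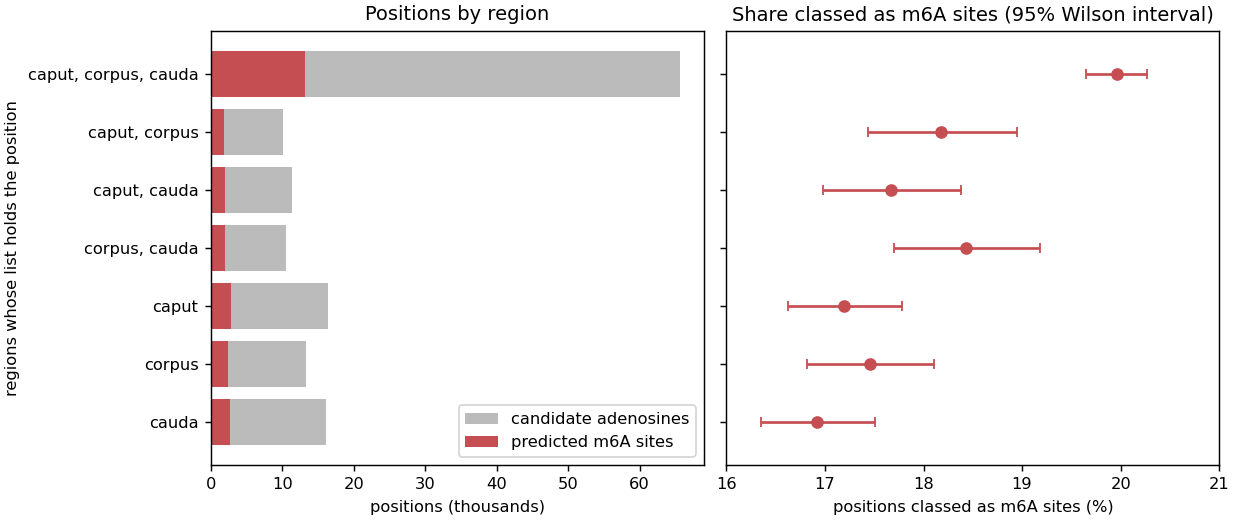
The left panel plots the number of candidate adenosines (grey) and of those classed as m6A sites (red) by the regions whose lists hold them. The right panel plots the percentage classed as m6A sites with 95% Wilson intervals on an axis from 16% to 21%, where the positions of all 3 regions lie at 20.0% and those of a single region between 16.9% and 17.5%.

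Positions that fell in the span of 1 gene (84.2% of all) belonged to 8740 genes. Candidate positions were listed in all 3 regions for 6109 genes, and in a single region for 499 genes of the caput list, 285 of the corpus list and 422 of the cauda list. Among the fixed gene lists, the caput genes of this kind included 4 of the 10 clear and narrow cell genes with candidates, where 0.698 were expected (exact stratified test, one-sided, p = 0.0024, adjusted p = 0.10 over 57 list tests). They were ATP6V1B1 and ATP6V1G3, subunits of the proton pump of acidifying cells, HEPACAM2 and STAP1. They also included 3 of 9 sperm and spermatid genes (Actl7b, CABS1 and CAPZA3; exact test, p = 0.0053, adjusted p = 0.10). In the cauda, the genes of this kind included 3 of 10 posterior HOX genes (HOXA10, Hoxa11 and HOXC10, regulators of position along the body axis; exact test, p = 0.0054, adjusted p = 0.10). None of these 3 lists passed after adjustment. The ontology term motile cilium, with 11 of 51 genes in the caput against 2.73 expected, did not pass either (exact test, p = 3.0e-05, adjusted p = 0.16 over 5394 term tests). A listing in a single region is not a measured difference. In the authors' deposited table, HOXC10 had log2 folds of 0.51 (cauda over caput) and -0.45 (cauda over corpus). Hoxa11 had 0.089 (cauda over caput) and STAP1 0.50 (corpus over caput), and none of these sites was called. Called sites of HOXA10, ATP6V1B1 and ATP6V1G3, given below, went in the direction of their listing.

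The comparison of the corpus with the caput asked which sites, here whole peaks, differ along the proximal duct. Such a peak need not hold an adenosine classed as an m6A site. Among positions assigned to 1 gene, HOXA10, ELSPBP1 and ATP6V1G3, named below, had candidates but 0 classed as m6A sites in any region. The same held for other genes named in these results, among them SEL1L2, Akap4, DNAI2, TXN, PDGFRA, Itga6, CRISP2, FCRL5, COG2 and Ubr4. A site of Tsks, a substrate of testis-specific kinases, was lower in the corpus by a log2 fold of -2.91 (adjusted p = 1.3e-08 in the authors' deposited table). Sites of 4 clear and narrow cell genes were also lower, namely ATP6V1B1 (log2 fold -1.35), ATP6V1G3 (-0.99), FOXI1 (-0.91) and DMRT2 (-0.32), with adjusted p from 1.1e-04 to 0.036 in the authors' deposited table. Another site of ATP6V1B1, on chromosome 9 from 32224892 to 32225138, had the largest absolute log2 fold of this list, 1.88 (adjusted p = 0.87 in the authors' deposited table), opposite in direction. A site of PTPRC, the leukocyte antigen CD45, was higher in the corpus by a log2 fold of 0.93 (adjusted p = 0.0055, the authors' deposited table). Its span held 6 candidates in the caput and 3 in the corpus. It was the 1 site called among 21 of the macrophage and lymphocyte list, whose median log2 fold was 0.026. That list did not pass (exact stratified test, one-sided, p = 0.22, adjusted p = 0.89 over 112 list tests).

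SEL1L2 (log2 fold -3.37) and CYLC1, a cylicin of the sperm head (-3.15), had a p listed as 0 in the authors' deposited table. Such a p stands for a log10 p of -434, where the next lowest in this comparison is -15.7 in the authors' deposited table, so it may be a placeholder and gives no measure of strength; 9, 3 and 1 sites of the comparisons, in the order given here, carry it.

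Of 14061 sites in 7973 genes, 419 passed an adjusted p under 0.05 in the authors' deposited table, 158 higher and 261 lower in the corpus. At an unadjusted p under 0.05, the authors' deposited table held 1014 higher and 1299 lower sites. Of these, 91 and 160 differed at least 2-fold. About 703 in all would be listed by chance if the p-values were uniform. They are not, since the largest is 0.83, and the test behind them is not given. The excess over 703 is therefore no count of true differences. The median log2 fold of all sites in the authors' deposited table was -0.02. The largest positive log2 folds at an unadjusted p under 0.05 were those of NSMCE1 (7.50, p listed as 0), AP1S2 (6.54, adjusted p = 0.21), KHSRP (4.75, adjusted p = 0.16), Rabep1 (4.65, adjusted p = 0.31) and TXN (3.95, adjusted p = 0.14) in the authors' deposited table. The 5 largest negative ones in the authors' deposited table were those of SEL1L2, CYLC1 and Tsks given above, GUCY1B1 (-2.94, adjusted p = 0.23) and RWDD1 (-2.82, adjusted p = 0.032). The SEL1L2 site spanned chromosome 12 from 83870380 to 83897570 on the plus strand and the CYLC1 site chromosome X from 74892873 to 74893022 on the minus strand, as the authors' deposited table gives them. Further lower sites, chosen after their values were seen, were those of ZNF474 (-2.18), SPZ1 (-1.23) and TTC16 (-1.15), each with an adjusted p of 4.0e-13 or listed as 0 in the authors' deposited table.

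By list, clear and narrow cell genes stood out. Of their 10 genes with a site, 4 had a lower site at adjusted p under 0.05 in the authors' deposited table, against 0.295 expected (exact stratified test, one-sided, p = 1.2e-04, adjusted p = 0.013 over 112 list tests). Of the 17 sites, 5 were lower and 0 higher when adjusted over the list alone. At an unadjusted p under 0.05, the threshold set before the data were examined, the list was not called (4 of 10 genes against 1.44 expected, exact test, p = 0.040, adjusted p = 0.64), nor was any other list in any comparison. The list test and its threshold were chosen after the data were seen, and over the 224 tests of both thresholds together the adjusted p of this list was 0.026. Multiciliated cell genes had 3 lower sites and 1 higher site among 7 (exact test of lower genes, p = 0.0066, adjusted p = 0.19), with TEKT1 at -1.48 and -0.45, DNAI2 at -0.40 and RSPH4A at 1.22 in the authors' deposited table. Adjusted over the list alone, the same counts of 3 and 1 were reached. Sperm and spermatid genes had 2 lower sites among 9 (exact test, p = 0.0097, adjusted p = 0.22), and 4 lower and 3 higher when adjusted over the list alone. Their lower sites were AKAP3 (-0.30) and Akap4 (-0.42), scaffold proteins of the sperm tail, both with an adjusted p of 0.014 in the authors' deposited table. Ion and water transport genes had 2 lower sites among 12 (also when adjusted over the list alone; exact test, p = 0.020, adjusted p = 0.38), CFTR (-0.98, adjusted p = 0.020) and CA12 (-0.86, adjusted p = 0.028) in the authors' deposited table. Epididymal secretory genes had 2 lower sites among 23, also when adjusted over the list alone, both in ADAM28, at -0.49 (adjusted p = 5.2e-07) and -0.019 (adjusted p = 0.025) in the authors' deposited table. The erythrocyte list had 1 gene with a site, HEMGN, which cannot stand for these cells. All 3 HEMGN sites were lower, at -2.08, -1.53 and -1.09 with adjusted p from 0.0022 to 0.0076 in the authors' deposited table. Its 26 candidate positions were listed in the caput alone. Single sites were lower in EMCN of the endothelium (-0.84, adjusted p = 0.025) and in the heat shock gene HSPA6 (-0.86, adjusted p = 0.036), and a site of the junction gene CGN passed (adjusted p = 0.038) at a log2 fold of 0.046 in the authors' deposited table. By the authors' test, 0 sites passed an adjusted p under 0.05 among the 21 sites of m6A writers (2 at an unadjusted p under 0.05), 4 of m6A erasers (0), 25 of m6A readers (4), 12 of beta-defensins (2), 11 of posterior HOX genes (1), 35 of smooth muscle genes (2), 28 of fibroblast genes (5), 19 of steroid genes (1), 10 of basal cell genes (1) and 15 of antioxidant genes (5) in the authors' deposited table. Adjusted over the list alone, 1 beta-defensin site was lower and 3 antioxidant sites and 1 fibroblast site were higher.

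The comparison of the cauda with the caput set the ends of the duct against each other. HOXA10 carried a site that was higher in the cauda by a log2 fold of 0.96 (adjusted p = 7.1e-06), on chromosome 4 from 56111679 to 56112074, minus strand, in the authors' deposited table. ADAM28, a metalloprotease-family gene of the secretory list, had sites that were lower at -2.26 (adjusted p = 3.4e-06) and -1.90 (adjusted p = 0.0058) and a site that was higher at 0.13 (adjusted p = 7.8e-05) in the authors' deposited table. DEFB118, a beta-defensin, had lower sites at -0.80 (adjusted p = 0.0048) and -1.57 (adjusted p = 0.0066), and a site of another gene of that name had a log2 fold of 0.38 (adjusted p = 0.15) in the authors' deposited table. Of the 6 beta-defensin sites, 2 were lower and 3 higher when adjusted over the list alone. Among genes of the m6A machinery, 1 of 18 writer sites and 1 of 30 reader sites passed the adjusted threshold, against 314 of 13826 sites overall. These were a site of the writer component Virma, higher by 1.02 (adjusted p = 0.043), and a site of the reader Fxr1, higher by 0.76 (adjusted p = 0.026), in the authors' deposited table.

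Of 13826 sites in 8070 genes, 314 passed an adjusted p under 0.05 in the authors' deposited table, 195 higher and 119 lower in the cauda. At an unadjusted p under 0.05 the authors' deposited table held 1457 higher and 923 lower sites, and 137 and 86 of them differed at least 2-fold. About 691 would be listed by chance if p-values were uniform, which they are not (largest p 0.80). The median log2 fold of all sites was 0.043 in the authors' deposited table. The 5 largest positive log2 folds at an unadjusted p under 0.05 were GALNT4 (3.86, adjusted p = 0.29), TRAPPC3 (3.42, 0.13), LMBR1 (2.53, 0.30), DICER1 (2.37, 0.19) and FCRL5 (2.36, 6.3e-05) in the authors' deposited table. The 5 largest negative ones were SNX9 (-3.85, adjusted p = 0.074), PDZD2 (-3.64, 2.1e-07), GUCY1B1 (-3.56, 0.35), Stx3 (-3.29, 0.31) and MAP2K1 (-3.07, 0.0066) in the authors' deposited table. Of these 10, the sites of FCRL5, PDZD2 and MAP2K1 passed the adjusted threshold in the authors' deposited table. A site of Hnf4a, chosen after its values were seen, was lower by a log2 fold of -0.63 (adjusted p = 1.9e-05) in the authors' deposited table.

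Epididymal secretory genes had 3 higher and 2 lower sites among 16 in the authors' deposited table, the higher ones in ADAM28, ELSPBP1 (0.33) and CRISP2 (0.47). With 3 of 11 genes higher against 0.252 expected, the list reached p = 0.0016 in the exact stratified test and an adjusted p of 0.059. The ADAM28 site counted as higher has a log2 fold of 0.13 with 17 candidates in the caput and 0 in the cauda, while the other called sites of the gene are lower in the authors' deposited table. With each gene counted in the direction of its lowest-p site, 2 of 11 genes were higher against 0.248 expected (exact test, p = 0.024, adjusted p = 0.45). Adjusted over the list alone, again 3 sites were higher and 2 lower. Among 14 posterior HOX sites, HOXA10 passed the adjusted threshold of the authors' deposited table, and 1 site was higher and 1 lower when adjusted over the list alone. Multiciliated cell genes had 2 lower sites among 14 (3 when adjusted over the list alone), both in RSPH4A (-1.46, p listed as 0, and -0.58, adjusted p = 0.0017) in the authors' deposited table. Among clear and narrow cell genes 1 of 10 sites was lower (2 lower and 1 higher when adjusted over the list alone), in DMRT2 (-0.76, adjusted p = 1.1e-06, the authors' deposited table). Single sites were lower in CA12 (-1.23), SYNM (-0.79), PDGFRA (-0.92), EMCN (-0.87) and HSPA1A (-0.29) and higher in GCLM (0.41), with adjusted p from 0.0046 to 0.048 in the authors' deposited table. HSPA1A has near-identical relatives, so reads can be shared between copies. By the authors' test 0 of the 13 sperm and spermatid sites passed, against 3 at an unadjusted p under 0.05 in the authors' deposited table, and 0 passed when adjusted over the list alone.

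The comparison of the cauda with the corpus addressed the distal duct. Of 9 beta-defensin sites, with a median log2 fold of 0.029, 3 were lower in the cauda, at -0.47 (adjusted p = 3.9e-04) and -0.88 (adjusted p = 0.0013) in DEFB119 and at -0.77 (adjusted p = 0.023) in DEFB118, in the authors' deposited table. HOXA10 was higher by a log2 fold of 1.03 (adjusted p = 0.0019) in the authors' deposited table. FXR2, an m6A reader, had a site that was lower at -0.50 (adjusted p = 0.020) in the authors' deposited table, the 1 called among 28 reader sites. Of the 20 writer sites, 0 were called. The spans of the DEFB118 site (chromosome 12, 54893355 to 54893547, plus strand) and of a DEFB119 site (54893534 to 54893783, minus strand) overlap in the authors' deposited table, so the pair cannot be counted as independent.

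Of 13917 sites in 7939 genes, 273 passed an adjusted p under 0.05 in the authors' deposited table, 173 higher and 100 lower in the cauda. At an unadjusted p under 0.05 there were 1352 higher and 930 lower sites in the authors' deposited table, and 120 and 68 of them differed at least 2-fold. About 696 would be listed by chance if p-values were uniform, which they are not (largest p 0.83). The median log2 fold of all sites was 0.046 in the authors' deposited table. Among the largest positive log2 folds at an unadjusted p under 0.05 were those of RWDD1 (4.87, adjusted p = 0.16), LMBR1 (3.92, 0.12), MINK1 (3.64, 0.22) and RTF2 (2.85, 0.041) in the authors' deposited table. The largest negative ones belonged to Rabep1 (-3.23, adjusted p = 0.28), COG2 (-3.06, 0.050), RBBP8NL (-2.93, 0.0049), CYLC1 (-2.53, 0.25) and Ubr4 (-2.37, 0.0074) in the authors' deposited table. Chosen after their values were seen, SV2C (2.10, adjusted p = 1.8e-08) was higher and SLC16A1, a monocarboxylate transporter, lower at 2 sites (-1.0, 3.0e-06, and -1.72, 7.8e-05) in the authors' deposited table.

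Beta-defensins had 3 lower sites among 9 in 2 of 6 genes, against 0.0592 expected (exact stratified test, one-sided, p = 0.0012, adjusted p = 0.059), and 3 lower and 1 higher when adjusted over the list alone. With the overlapping DEFB118 and DEFB119 sites counted once, 1 of 6 genes was lower against 0.058 expected (exact test, p = 0.057, adjusted p = 0.67). Multiciliated cell genes had 1 lower site, in TPPP3 (-0.71, adjusted p = 0.0085), and 1 higher, in TEKT1 (1.34, adjusted p = 0.013), among 5 in the authors' deposited table, and 3 higher and 1 lower when adjusted over the list alone. Single sites were lower in ROS1 (-0.77), Itga6 (-0.59) and PDGFRA (-0.77) and higher in ELSPBP1 (0.25) and GSTO1 (0.21), with adjusted p from 0.022 to 0.044 in the authors' deposited table. A site of EMCN passed the adjusted threshold (0.0016) with a log2 fold of 0.011 in the authors' deposited table, a size at which its direction carries little weight. The 3 sites of the fixed eraser list included ALKBH3 (0.54, adjusted p = 0.062) and ALKBH5 (0.48, adjusted p = 0.069) in the authors' deposited table. Neither was called, and both passed when adjusted over the list alone, which corrects for these 3 sites only. By the authors' test 0 of the 8 sites in clear and narrow cell genes (3 at an unadjusted p under 0.05) and 0 of the 2 in lipocalins (0) passed the adjusted threshold of the authors' deposited table. Among ontology terms and pathways, actin filament binding was the 1 term to pass: 29 of its 93 genes had a lower site at an unadjusted p under 0.05 in the authors' deposited table, against 12.2 expected (exact stratified test, p = 1.4e-06, adjusted p = 0.029 over 19924 term tests). At an adjusted p under 0.05, 0 of the 93 genes had a lower site in the authors' deposited table, against 1.5 expected (adjusted p = 1).

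**Figure D2:**
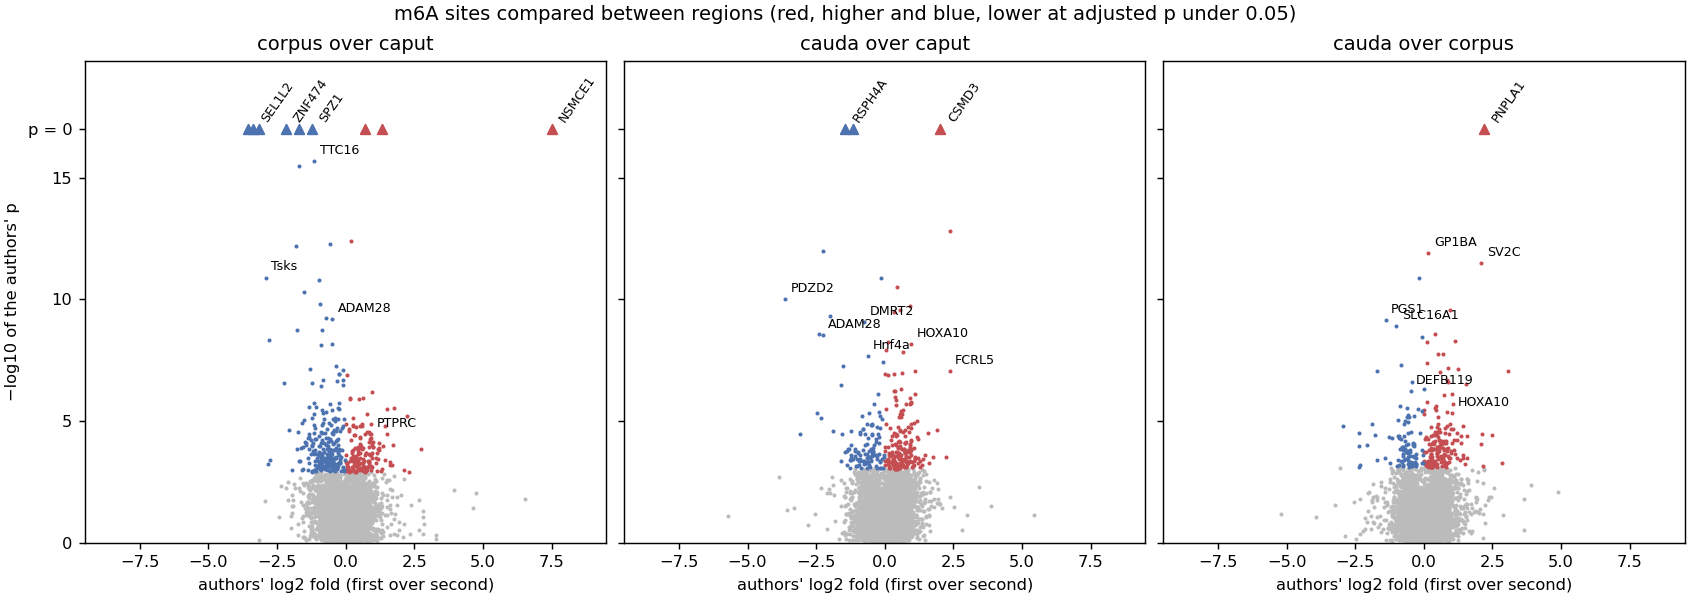
Each point is a site of the authors' deposited table, with the log2 fold of the first-named over the second-named region on the horizontal axis and −log10 of the authors' p on the vertical axis. Red and blue points are the 158 higher and 261 lower (corpus over caput), 195 and 119 (cauda over caput) and 173 and 100 (cauda over corpus) sites at adjusted p under 0.05, and triangles are sites with p listed as 0.

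**Figure D3:**
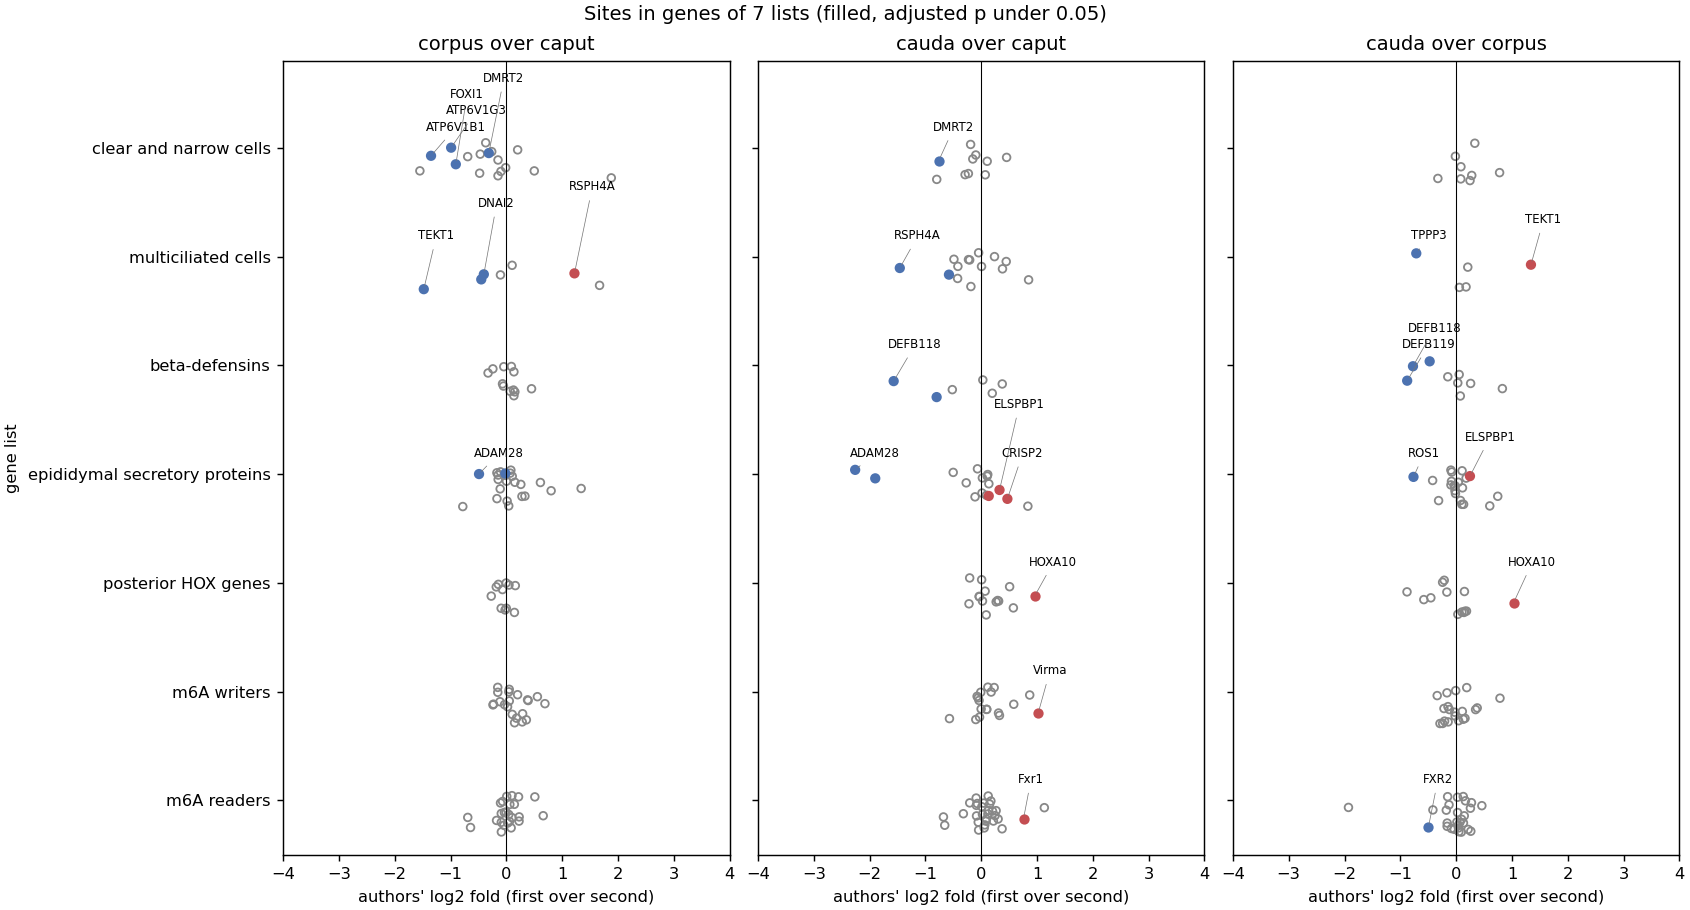
Each point is a site in a gene of 7 fixed lists, placed by its log2 fold in the authors' deposited table and shifted vertically at random for legibility. Filled points passed an adjusted p under 0.05 (red higher, blue lower, 1 label per gene), among them 4 clear and narrow cell sites in the corpus over caput panel and HOXA10 at 0.96 and 1.03 in the panels of the cauda.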

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

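The alternatives that count every line, use positions, leave out folds near 1 or vary the list and term tests were chosen after seeing the data. With high and very high confidence classes only, predicted sites numbered 7789 (caput), 7624 (corpus) and 7829 (cauda), and with every line counted 43551, 42646 and 43860. Shared peaks fell from 79.1% to 58.5% (corpus with caput), from 77.6% to 57.2% (cauda with caput) and from 76.0% to 55.9% (cauda with corpus) under reciprocal overlap, since it asks for more overlap. Counted as positions they were 76.1%, 74.3% and 73.5%, and with high confidence peaks cauda with corpus was 77.5%. At an adjusted p under 0.05 higher and lower sites numbered 158 and 261 (corpus over caput), 195 and 119 (cauda over caput) and 173 and 100 (cauda over corpus). With p under 0.05 and at least a 2-fold change they numbered 91 and 160, 137 and 86, and 120 and 68. These counts fall because fewer sites can pass. The clear and narrow cell call was lost with sites at an unadjusted p (exact test, adjusted p = 0.64, against 0.012 to 0.015 under the other alternatives), as was actin filament binding at an adjusted p (adjusted p = 1); the cause was not tested. The other 31 values kept their side of the threshold or stayed within 1.5 times or their interval, though adjusted p rose from 0.059 to 0.67 for beta-defensins with overlapping sites counted once and to 0.45 for secretory genes by lowest-p site (exact tests). No paired analysis was possible because the tables carry no library values. For the same reason no replicate could be left out, and the alternatives set beforehand for expression values and motifs were not run. Depth per site is unknown, so no limit from depth can be given.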

Other observations

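All tests in this part were chosen after the results were seen. Genes whose candidate positions were listed in a single region include, in the caput, C22orf46 (64 positions), CCDC110 (57), PDCL2 (43) and ADAM28 (35). In the corpus they include KNSTRN (32), KIZ (29) and NUP50 (26), and in the cauda GP1BA (28), NBEA (27), NRK (17) and the complement gene C3 (17). The sperm-binding gene ELSPBP1 (5) and the spermadhesin SPADH1 (6) were listed in the cauda. Among the corpus genes of this kind 12 of 144 belonged to innate immune response, against 4.72 expected (exact test, p = 0.0020, adjusted p = 1 over 5394 term tests).

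Fold and p did not always go together in the authors' deposited table. Among sites at adjusted p under 0.05, 18, 15 and 17 in the 3 comparisons had an absolute log2 fold under 0.1. Of 67 unspliced sites at adjusted p under 0.05 with candidates in the caput and none in the corpus, 58 had a lower fold in the corpus and the other 9 did not. C22orf46 had p listed as 0 and a log2 fold of 1.31 at a site with 43 candidates in the caput and 0 in the corpus, and -1.79 at another site, in the authors' deposited table. RSPH4A had a log2 fold of 1.22 at a site with 2 candidates in the caput and 0 in the corpus, in the authors' deposited table.

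Sites called lower in the corpus than in the caput lay in 235 genes. A candidate explanation is that the whole transcript was less abundant in the corpus, which would lower the other sites of the same genes too. In the 152 genes with other sites, the median log2 fold of those 301 sites was -0.072 (95% bootstrap interval over genes -0.11 to 0.010), against -0.67 at the lowest-p sites, which were selected for being low. Sites of the same gene showed no shared movement in this comparison (intraclass correlation 0.020, 95% bootstrap interval -0.014 to 0.057, 3504 genes), so the other sites decide nothing, and 83 genes have no other site: abundance and methylation cannot be told apart. RNA of male germ cells in the caput libraries may contribute. It stays open because the sperm and spermatid list has few genes with sites (exact test, adjusted p = 0.22) and a median log2 fold of 0.14 over its 9 sites. In the authors' deposited table AKAP3 was at -0.30 and 0.58 and Odf2 at -0.29 and 0.23. On the other side, Tsks and CYLC1 were among the lowest folds. Genes listed in the caput alone included 8 of 31 acrosomal vesicle genes against 2.22 expected, which did not pass (exact test, p = 7.8e-04, adjusted p = 0.82 over 5394 term tests). They also included 3 of 9 sperm and spermatid genes against 0.434 expected (exact test, p = 0.0053, adjusted p = 0.10 over 57 list tests). The corpus alone and the cauda alone each had 0 of these 9. One of the 3, CABS1, also belongs to motile cilium, so cilium and sperm genes are not separate sets here.

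Sites of clear and narrow cell genes were lower in the corpus than in the caput. Fewer of these cells in the corpus, or fewer of their transcripts, is a candidate explanation that would lower the sites of the whole list. The median log2 fold of the 17 sites was -0.32 (95% bootstrap interval over 10 genes -0.48 to -0.12) and 14 of them were below 0, but they include the 4 called sites that raised the pattern. Among the 13 others, 10 were below 0 with a median of -0.15, and sites of ATP6V1B1 went both ways (-1.35 and 1.88, adjusted p = 0.014 and 0.87, the authors' deposited table). Since sites of the same gene showed no shared movement, these values cannot decide it, and lower methylation of these transcripts stays open too, as untested.

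Positions listed in a single region were classed as m6A sites less often than positions listed in all 3. Peak edges that differ between regions could produce this, but positions of peaks with no shared position still lay 2.37 percentage points lower (difference -2.37, 95% bootstrap interval -3.02 to -1.67). Different genes in the sets of positions do not account for it either: within 3536 genes holding both kinds the mean difference was -3.29 points (permutation test, two-sided, p = 1e-05, the smallest that 100000 resamples can give). Less reliable peaks and weaker methylation in the single-region set both stay open, and no biological explanation was tested.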
